A study of Mus musculus with 8 samples.

How the data were processed

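Mouse embryonic stem cells were labelled with BrdU for 2 h, stained with propidium iodide and sorted into early and late S phase, and BrdU-labelled DNA from 40000 cells per fraction was immunoprecipitated and sequenced, per the labels' protocols. The labels refer to an earlier publication for cell culture and treatment and give no other detail of them. The samples were grouped by their descriptions into control and dTAG, with an early and a late fraction for each of 2 replicate numbers, so 8 samples stand behind 4 profiles. The first replicate of each group carries no number in its labels and was called replicate 1. For dTAG replicate 1 the letter in the sample titles and the fraction given in the labels disagree on which sample is early and which is late. The dTAG 1 profile correlated positively with the other 3 profiles, so this conflict did not turn its direction in the deposited scores.

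Bowtie2, SAMtools, bedtools and the mm10 build are named in the submitters' processing notes, and their versions are not given in the sources used here. The deposited values are a signed score per 5 kb position, with 1 column for each profile. Per the file headers and name, the score was smoothed with Loess and quantile normalized by the authors. The formula, the log base and the direction of the score are not stated. High scores were read as early. Of the windows with ribosomal protein genes, a housekeeping group, 98.8% scored above 0, against 4.17% of those with long neuronal and fragile-site genes. Tests had been planned for log2 ratios of early over late, and because the log base is not stated, all differences are given in score units. The sorted values of control 1 and dTAG 1 were identical, those of dTAG 1 and the sign-turned values of dTAG 2 were identical, and control 2 and dTAG 2 agreed to within 0.000114 over shared positions. In 4 positions some but not all profiles had a value, and those were left out. Smoothing makes neighbouring positions share reads, so windows are not independent measurements, and quantile normalization fixes the spread of each profile. No read counts or depths were used here.

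Scores were averaged over windows of 50 kb on 19 autosomes and chromosome X, with values in at least 0.5 of the 10 positions of a window. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, 2-sided, Benjamini-Hochberg, threshold 0.05). The replicate number was added as a block in a further model, because the mirrored distributions show that the authors' processing differed between replicate numbers. The labels do not say that a number marks a shared day or culture. Whole profiles were compared by Pearson r, windows by whether both dTAG profiles lay at least 0.5 above or below both controls, by a change of sign, by deciles of the mean over all 4 profiles, and by chromosome. Local maxima and minima and the correlation at fixed distances were computed with scipy 1.17.1 under Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

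Gene positions came from a table of RefSeq genes on GRCm38.p6, the assembly behind mm10. The table gives no strand, so each gene took the score at its midpoint instead of its transcription start, as had been planned. Scores were found for 21431 genes, and 215 protein-coding genes had none at their midpoint. Of 20 gene lists 19 were tested; the list of promoters with a YY1 motif and a correction for GC content need a genome sequence and were not run. The lists were pluripotency, formative and primed epiblast, neural, mesoderm, endoderm, trophoblast and 2-cell-like markers, Hox genes, ribosomal protein, oxidative phosphorylation, architectural and Polycomb, and DNA replication genes, replication-dependent histone genes, imprinted genes, the X-inactivation centre, olfactory and vomeronasal receptors, clustered protocadherins, and long neuronal and fragile-site genes. All listed symbols were matched except 1 each in the epiblast, mesoderm, X-inactivation and long gene lists, and 4 olfactory and 4 vomeronasal receptor genes had no score at their midpoint. Genes of a list in the same 50 kb window counted as 1 unit. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with fry and by 10000 rotations of the difference profile along the genome. Receptor, Zscan4 and histone families hold near-identical copies, at which reads can be shared between members.

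The named genes followed a rule set before the data were examined, as were the groups, tests, gene lists and most other settings: with fewer than 10 called regions, the 5 highest and 5 lowest stretches of 500 kb by mean difference among those in which all 4 differences between a dTAG and a control profile had the same sign, with up to 3 of their longest protein-coding genes. All pluripotency genes, the member with the highest and the lowest moderated statistic of every other list, and Yy1 and Etv4 were named as well. Not every gene that this rule selects is given here. Each window and stretch test was checked on simulated profiles in which 200 windows were changed by 1, 2 or 4 units, and the list test on simulated genes in which the pluripotency list was moved by 1 unit. That list was called and 0 of the 18 unmoved lists were. The simulated genes varied independently and without the replicate offset, so this check cannot show how often lists of correlated genes are falsely called. For windows of 50 kb with the replicate offset, the blocked model gave 14 false calls among 51425 windows, and for stretches of 500 kb it recovered 97.0% of changes of 1 unit with 1 false call, whereas the model without the block recovered 0% of changes of 2 units. The simulated windows also varied independently, with variances drawn from the distribution that the blocked model had fitted. These counts therefore cannot show how often the blocked model falsely calls windows of the deposited, smoothed scores. Alternatives covered the window size, the chromosomes used, scaling and centring of each profile, the variance model, thresholds, the replicate block, and each profile left out in turn. Bringing all profiles to one distribution, the blocked model with a trended and robust variance, the blocked tests of windows of 100 to 1000 kb, the stretches of 500 kb without 1 profile, camera with both the block and an estimated correlation, and the correlation of the differences within the replicate numbers were chosen after seeing the data.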

Results

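Replication timing was profiled in mouse embryonic stem cells with and without depletion of YY1, a zinc finger transcription factor that binds promoters and enhancers and can bridge them in chromatin loops. In this assay, Repli-seq, DNA made during a pulse of the nucleotide analogue BrdU is recovered from cells sorted into early and late S phase, so that each locus can be placed on a scale from late to early replication. YY1 was depleted with dTAG, a small molecule that marks a tagged protein for degradation, and cells were collected 2 days after treatment. The 8 samples formed 4 profiles, each built from an early and a late fraction: 2 control profiles and 2 dTAG profiles, numbered 1 and 2 within each group. Each profile gave a timing score, high where replication was early, at 514246 to 514248 of 526745 positions spaced 5 kb apart on mm10. Scores carry no read counts, so the depth behind each value is unknown and no counting error was attached. Nothing in the labels says that the replicates came from separate cultures, and p-values measure only the spread between these samples. YY1 itself was not measured here: the profiles give the timing of its gene, not the amount of protein.

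The question was where in the genome replication moved earlier or later without YY1, within a series concerned with DNA elements that set when and where replication takes place. Whole profiles were similar with and without dTAG, whichever were paired. Over 51425 windows of 50 kb, dTAG 1 correlated with control 1 at r = 0.993 and dTAG 2 with control 2 at r = 0.985, where windows along one genome are not independent replicates. Replicates of a group were less alike, at r = 0.970 between the controls and r = 0.969 between the dTAG profiles. The remaining pairs, control 1 with dTAG 2 and control 2 with dTAG 1, gave r = 0.965 and r = 0.967. The median size of the dTAG minus control difference was 0.20 score units, and 86.3% of windows differed by less than 0.5, while the median SE of the difference was 0.42. limma called 0 of the 51425 windows at an adjusted p of 0.05, with 500 windows at an unadjusted p under 0.05 where 2571 would be expected by chance. With 1 profile left out it called 0 windows without control 1, 0 without control 2, 3 without dTAG 1 and 4 without dTAG 2, but each of these fits sets 1 profile against 2 and takes its variance from those 2 alone.

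The replicate number divided the profiles more strongly than the treatment. The sorted scores of control 1 and dTAG 1 were identical, and those of dTAG 2 were the same set of numbers with the sign turned, so the authors' processing had given the replicate numbers mirrored distributions with means of 0.20 and -0.20. Between the replicate numbers limma called 15507 windows, 12715 of them lower in replicate 2, and with all profiles brought to one distribution 7256, of which 3935 were higher and 3321 lower. Values within each replicate number, dTAG 1 minus control 1 and dTAG 2 minus control 2, are therefore given beside many of the comparisons. Leaving out 1 profile unbalances the replicate numbers and moves the whole genome: the median difference of all genes was -0.02 with all profiles, 0.19 without control 1, -0.22 without control 2, -0.27 without dTAG 1 and 0.21 without dTAG 2. Differences and directions without 1 profile carry this offset. With the replicate number as a block, limma called 0 windows, the smallest adjusted p was 0.231, and 6224 windows had an unadjusted p under 0.05. With a trended and robust variance in the blocked model, a setting chosen after seeing the data, limma called 1462 windows, 466 earlier and 996 later after dTAG. The same setting called 0 windows for the crossed split, control 1 and dTAG 2 against control 2 and dTAG 1. With 4 profiles the blocked model takes its error from that crossed difference, and the crossed test takes its error from the dTAG difference. The 0 crossed calls are therefore no independent check of the 1462. The model without the block called 0 with either variance. In simulated profiles with this offset between replicate numbers, the model without the block recovered 0% of the windows changed by 4 units, whereas the blocked model recovered 80.6% of those changed by 2 units, 100% of those changed by 4 and 0% of those changed by 1. The simulated windows varied independently, with variances from the blocked fit, so these shares need not hold for the deposited, smoothed scores.

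Of the stretches of 500 kb that stood furthest apart between the groups, none passed the test without the block and with all profiles. On chromosome 13 from 5.5 to 6 Mb, at the gene for the zinc finger factor Klf6, the score was 0.99 ± 0.32 (SD, n = 2) after dTAG and -0.45 ± 0.56 in the control, with differences of 1.26 and 1.60 within the replicate numbers. On chromosome X from 147 to 147.5 Mb, at the serotonin receptor gene Htr2c and the interleukin receptor gene Il13ra2, it was -0.46 ± 0.29 after dTAG and -1.89 ± 0.43 in the control (1.33 and 1.53). On chromosome 15 from 91.5 to 92 Mb, at Lrrk2, which encodes a kinase mutated in inherited Parkinson disease, and Smgc, the scores were -2.11 ± 0.75 and -3.63 ± 1.16 (1.23 and 1.80). The stretch of chromosome 10 from 26.5 to 27 Mb, with Arhgap18 and the predicted gene Gm30534, scored 1.28 higher after dTAG (0.96 and 1.61). A stretch of chromosome 8 from 55 to 55.5 Mb, with 11 predicted protein-coding genes such as Gm51571, had the widest gap of the earlier stretches, 1.91, but it rested more on replicate 1 (2.94) than on replicate 2 (0.88). Leaving out control 2 took the difference to 0.50 at Arhgap18 and 0.70 at Lrrk2, and leaving out control 1 took them to 2.07 and 2.33. On chromosome 8 it was 0.84 without dTAG 1 and 2.97 without dTAG 2, where it passed the limma test without the block (adjusted p 0.0390).

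In the opposite direction, the stretch of chromosome 12 from 77.5 to 78 Mb scored -1.51 ± 0.33 (SD, n = 2) after dTAG and 0.46 ± 0.47 in the control, with -1.40 and -2.53 within the replicate numbers, and it held no midpoint of a protein-coding gene. On the same chromosome, the stretch from 61.5 to 62 Mb at Lrfn5, a gene for a synaptic adhesion protein, scored -2.91 ± 0.24 after dTAG and -1.19 ± 0.32 in the control (-1.66 and -1.77). The stretch from 33 to 33.5 Mb, with Atxn7l1, Cdhr3 and Twistnb, scored -0.08 ± 0.75 and 1.51 ± 0.75 (-1.58 in both). At Suclg2, a mitochondrial succinyl-CoA ligase gene on chromosome 6 from 95.5 to 96 Mb, the score was 1.79 lower after dTAG (difference -1.79), with -0.70 in replicate 1 and -2.88 in replicate 2. At Arhgef6, Vgll1 and Gm364 on chromosome X from 57 to 57.5 Mb, the scores were -3.16 ± 0.98 after dTAG and -1.37 ± 0.20 in the control (-1.24 and -2.34). Without dTAG 2 the differences were -1.14 at Suclg2 and -1.10 at Arhgef6, and without control 1 that at Atxn7l1 was -1.05. Without the block limma called 0 of 5145 stretches, with 37 at an unadjusted p under 0.05 where chance gives 257. With the replicate block it called 330 stretches, 147 earlier and 183 later, among them all 10 named here, with adjusted p from 1.48e-05 at Lrfn5 to 0.00126 at Suclg2. The blocked count depended on the setting: it was 281 of 12860 windows of 200 kb and 0 of 6430 windows of 400 kb, or 964 and 135 with the trended and robust variance. For 500 kb it was 441 with that variance, 4 with all profiles brought to one distribution and 0 with each profile centred on its chromosome means.

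**Figure D1:**
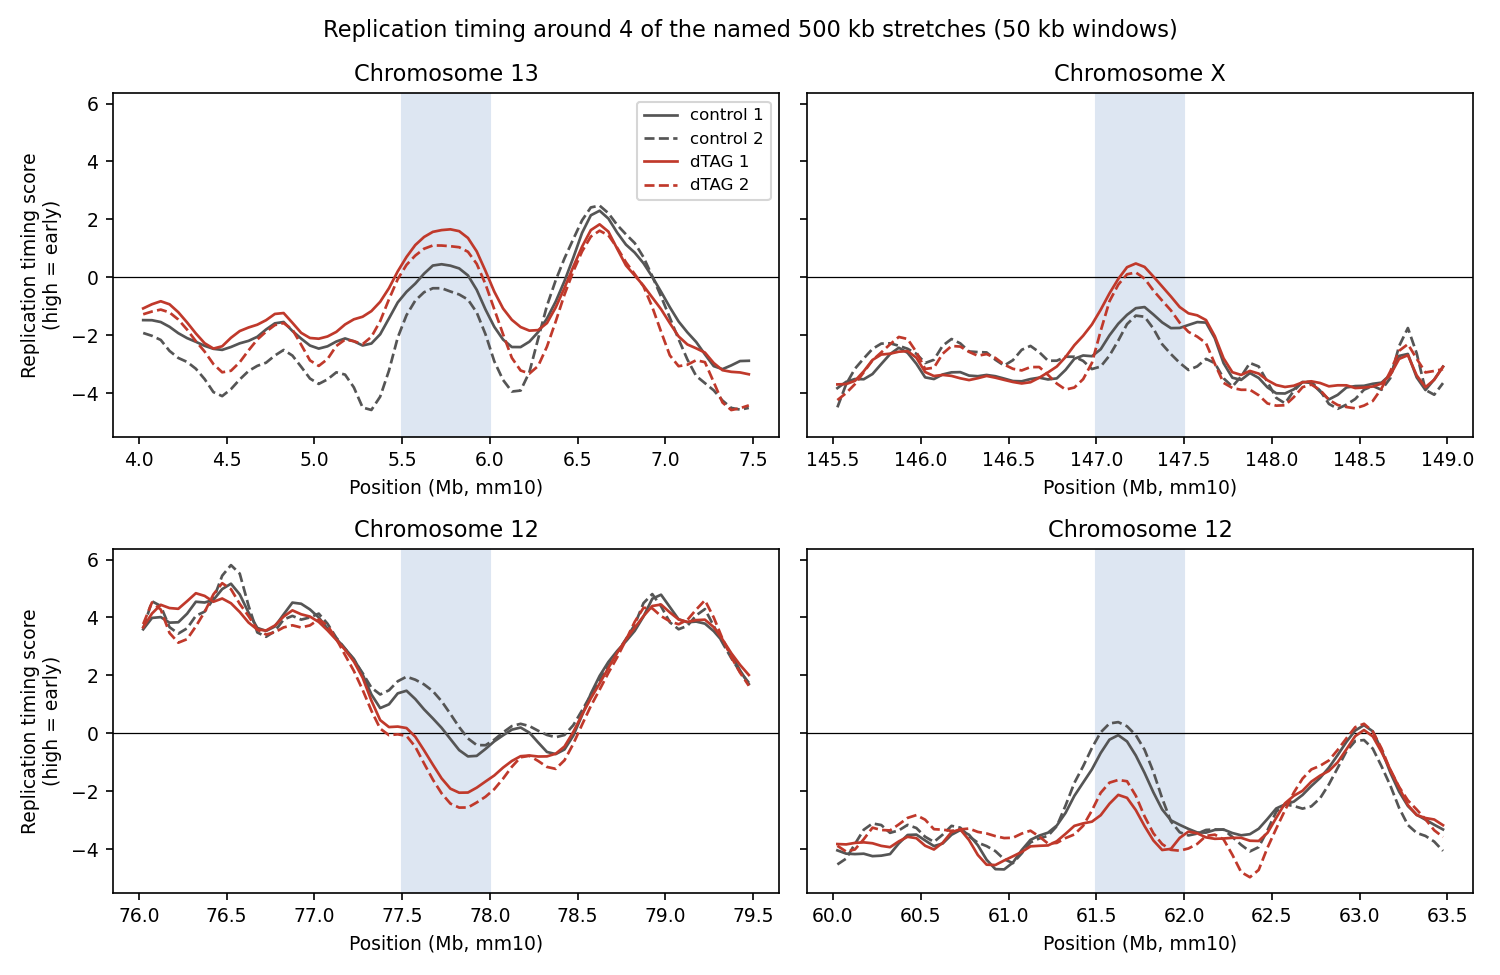
Replication timing score (vertical axis, score units, high = early) against position on mm10 (horizontal axis, Mb) around 4 of the named stretches, which are shaded; each line is 1 profile in windows of 50 kb, control in grey and dTAG in red, replicate 1 solid and replicate 2 dashed. Both dTAG lines lie above both control lines in the shaded parts of chromosomes 13 and X and below them in those of chromosome 12.

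Windows in which both dTAG profiles lay on the same side of both controls by at least 0.5 units numbered 834, of which 273 were earlier and 561 later after dTAG. Joined over gaps of up to 100 kb, the earlier windows made 89 regions with a median size of 100 kb and a total of 13.65 Mb, and the later windows made 125 regions with a median size of 200 kb and a total of 28.05 Mb. The earlier windows averaged -1.70 in the control and -0.68 after dTAG, with mean differences of 0.90 and 1.14 within the replicate numbers, and the later windows averaged -0.28 and -1.45, with mean differences of -0.98 and -1.37. The midpoints of the imprinted genes Snrpn and Ndn, the respiratory complex I gene Ndufa5 and the dystrophin gene Dmd lay in later windows. Dmd is longer than the later region at its midpoint, which spanned 250 kb. No pluripotency, Hox or histone gene had its midpoint in a window of either kind. Those lists cover 26, 13 and 13 windows, and 1.62% of all windows were shifted, so their absence is close to what chance gives. Splitting the profiles by replicate number gave 16117 such windows, and the crossed split gave 81. With all profiles brought to one distribution these counts were 10611 and 129, and dTAG against control gave 1180. With 4 profiles there are 3 splits into equal groups, so no exact permutation test can give a p below 0.333. With 1 profile left out fewer profiles have to agree, and the count was 6811 without control 1, 3720 without control 2, 7374 without dTAG 1 and 3651 without dTAG 2. Of these 4999, 617, 1808 and 2723 were earlier, which follows the offset between replicate numbers, so these counts do not test the direction after dTAG. At a threshold of 0.25 units 1262 of 2780 windows were earlier. With no minimum size, both dTAG profiles lay above both controls in 5585 windows and below both in 4389. The excess of later windows was therefore limited to the larger shifts.

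Shifted windows were most frequent in the middle of the timing scale, with more on its late side than on its early side. Windows were divided into deciles from the latest (decile 1) to the earliest (decile 10). Of decile 5 4.92% and of decile 4 4.34% were shifted by at least 0.5, against 0.369% of the latest decile and 0.175% of the earliest. Deciles 3 and 6 had 1.71% and 2.84%, and deciles 7 and 8 had 1.11% and 0.175%. The mean difference was 0.01 in the latest decile (0.02 and 0.00 within the replicate numbers) and -0.05 in the earliest (-0.02 and -0.08). Because both profiles of a replicate number hold the same set of scores, these means are held near 0 and cannot show whether the early or the late part of the genome moved as a whole. The lowest and highest of the 10 means were -0.05 in decile 10 and 0.04 in decile 9. Leaving out 1 profile unbalanced the replicate numbers and moved the mean of the latest decile to between -0.24 (without dTAG 1) and 0.26 (without dTAG 2), and that of the earliest to between -0.30 (without dTAG 1) and 0.21 (without dTAG 2). Without control 1 these means were 0.25 and 0.17, and without control 2 they were -0.23 and -0.27.

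**Figure D2:**
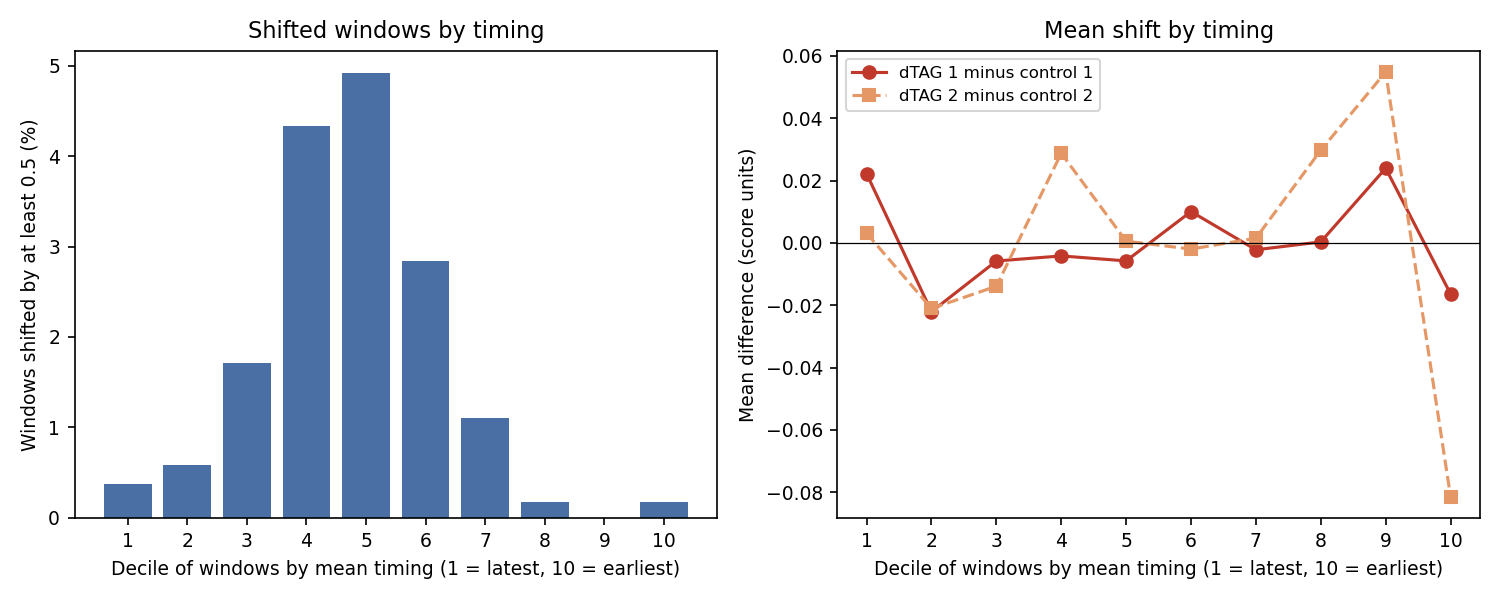
Left, percent of windows of 50 kb shifted by at least 0.5 score units in each decile of timing from latest (1) to earliest (10); right, mean difference in score units per decile for dTAG 1 minus control 1 (circles) and dTAG 2 minus control 2 (squares). The bars reach 4.92% in decile 5, and the mean differences lie between -0.08 and 0.05.

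Few windows crossed from one side of the scale to the other. Both controls were early (score above 0) and both dTAG profiles late in 180 windows, and the reverse held in 158, together 0.657% of all windows. All of these had a mean score within 1 unit of 0, and the median size of their difference was 0.70. The same count was 1105 between the replicate numbers, 1046 of them early in replicate 1 and late in replicate 2, and 46 for the crossed split. On one distribution the replicate numbers gave 320 early to late and 306 late to early, and dTAG against control gave 225 and 209. For dTAG against control the deposited count was 37, of which 8 were late to early, when windows with any score within 0.25 of 0 were left out. Without 1 profile it was 1003 (control 1), 886 (control 2), 950 (dTAG 1) or 846 (dTAG 2), of which 708, 211, 269 and 626 were late to early, again in the direction of the offset. By chromosome, the mean difference was highest on chromosome 13 at 0.09, of which replicate 1 gave 0.02 and replicate 2 gave 0.17, and lowest on chromosome X at -0.05, with -0.01 and -0.10. On chromosome 12 it was -0.05 in both, and 77 of its 83 shifted windows were later, while its median window differed by 0.03. Leaving out 1 profile moved the chromosome 13 mean to 0.41 (without control 1), -0.23 (without control 2), -0.15 (without dTAG 1) and 0.34 (without dTAG 2), and the chromosome X mean to 0.02, -0.13, -0.18 and 0.07 in the same order.

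Genes of the pluripotency network replicated early with and without YY1. All 26 members scored above 0, with a mean of 3.51 in the control, and the median difference was -0.03, with 0.05 in replicate 1 and -0.22 in replicate 2. Pou5f1, the gene for the core stem cell factor OCT4, scored 3.69 ± 0.56 (SD, n = 2) after dTAG and 3.81 ± 0.39 in the control. Its partners Sox2 and Nanog scored 3.93 ± 0.13 against 3.77 ± 0.20 and 3.17 ± 0.84 against 3.23 ± 0.27. The member furthest below its control value was the nuclear receptor gene Nr0b1 on chromosome X, at 0.24 ± 0.20 against 0.79 ± 0.27, followed by Esrrb, another nuclear receptor gene, at 3.73 ± 0.31 against 4.09 ± 0.31. The neighbours Dppa2 and Dppa4 on chromosome 16 differed by -0.28 and -0.29. The difference at Fgf4 was 0.29 but had opposite signs in the replicate numbers. limma called 0 members among all 21431 genes and 0 adjusted over the list alone, and for the list as a whole camera, limma's competitive set test, gave an adjusted p of 0.602. Over all genes 172 had an unadjusted p under 0.05 and 1607 with the replicate block, which also called 0, where chance gives 1072.

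Yy1 itself and Etv4, a gene with YY1 bound at its promoter in mouse embryonic stem cells, also kept early scores. Yy1 scored 4.28 ± 0.29 (SD, n = 2) after dTAG and 4.69 ± 0.21 in the control, a gap that came from replicate 2 (-0.76) more than from replicate 1 (-0.06). Etv4 scored 4.66 ± 0.63 and 4.71 ± 0.01, and its difference had opposite signs in the replicate numbers. Neither gene passed the limma test.

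4 of 19 tested gene lists scored earlier after dTAG by camera with its preset correlation, and none kept the call with an estimated correlation. The estimate rests on the few residual degrees of freedom of 4 profiles, so that setting could hardly call any list. In it the vomeronasal receptors lost the call although their estimated correlation, -0.0020, was below the preset value. A call lost in that setting alone therefore does not decide for or against a list. Among 2-cell-like markers, genes of the totipotent-like state, the median difference was 0.59, with 1.05 in replicate 1 and 0.14 in replicate 2, and it was 0.15 without dTAG 1 and 1.06 without dTAG 2, where all genes had -0.27 and 0.21. Zscan4e scored -0.04 ± 0.72 (SD, n = 2) after dTAG and -0.90 ± 0.22 in the control, while Usp17la differed by -0.34. The camera adjusted p was 1.50e-04, and the adjusted p = 0.978 with an estimated correlation. Of the 10 genes, 7 lay on chromosome 7, 2 on chromosome 13 and 1 on chromosome 4. Neighbouring windows share smoothed scores, so camera with its preset correlation can overstate the evidence from these 10 units. Replication-dependent histone genes, 54 of 64 on chromosome 13 and 10 on chromosome 3, had a median difference of 0.67 that came from replicate 2 alone, 0.00 against 1.33, and that was -0.03 without control 2 and 1.26 without control 1, where all genes had -0.22 and 0.19. Their adjusted p was 1.08e-06, and the adjusted p = 0.978 with an estimated correlation. H4c18 differed by 0.69 and H2bc1 by 0.23.

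Olfactory receptor genes, a large family of clustered odorant receptors that is silent in stem cells, had a median difference of 0.15 over 576 windows, with 0.06 in replicate 1 and 0.25 in replicate 2. In 263 of these windows both differences were above 0 and in 96 both were below. The adjusted p was 7.33e-08 by camera and 0.978 with an estimated correlation, and rotating the difference profile along the genome gave an adjusted permutation p of 0.0133. The rotations were not matched on timing, and these genes had a control mean of -0.89. Differences varied more over windows in deciles 4 and 5 (SD 0.53 and 0.49) than in deciles 8 and 9 (0.21 and 0.19). Rotated medians may therefore spread too little for these genes, and the permutation p may be too small. Olfr697 on chromosome 7 scored -1.05 ± 0.28 (SD, n = 2) after dTAG and -2.58 ± 0.34 in the control, and Olfr47 on chromosome 6 scored -3.76 ± 0.17 and -2.11 ± 0.62. Vomeronasal receptor genes, which detect pheromones, had a median difference of 0.12 (0.14 and 0.10 within the replicate numbers), from 1.16 at Vmn2r4 to -0.93 at Vmn1r47. Their adjusted p was 1.50e-04 by camera and 0.288 with an estimated correlation. By rotation the adjusted permutation p was 0.0994 for the 2-cell-like markers, 0.0994 for the histone genes and 0.120 for the vomeronasal receptors. limma's self-contained set test fry called none of the 19 lists, with a smallest adjusted p of 0.936. Leaving out 1 profile ended the camera call of the 2-cell-like markers without control 1 (adjusted p 0.0612) and without dTAG 1 (0.215), that of the histone genes without control 2 (0.156), and that of the vomeronasal receptors without control 1 (0.617) and without dTAG 2 (0.104), the last 2 in the opposite direction. The olfactory receptors kept the call without control 2 (0.00500) and without dTAG 1 (1.09e-05), with medians of -0.11 and -0.01 where the median of all genes was -0.22 and -0.27.

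The other 15 lists did not pass camera on the deposited scores with 1 gene per window and no block, and no member of any list was called, adjusted over all genes or adjusted over the list alone. Hox genes, the early replicating body plan regulators, had a median difference of 0.21 (-0.02 in replicate 1 and 0.47 in replicate 2), with a camera adjusted p of 0.119. It was 0.0400 with the replicate block, 0.00482 with every gene of the list counted, 0.0433 with each profile scaled by its median absolute deviation, 0.0343 with chromosome centring, 0.0396 on one distribution, 0.000438 without control 1 and 0.798, in the opposite direction, without control 2. The adjusted p was 0.978 with an estimated correlation and 0.894 with that and the block. Hoxb2 differed by 0.73 (0.28 and 1.18), and by 0.17 without control 2 and 1.28 without control 1. Genes of the X-inactivation centre had a median of 0.18 (0.15 and 0.19), from 0.45 at Zcchc13 to -0.03 at Jpx, and an adjusted p of 0.0857. It was 0.0225 with chromosome centring, 0.0197 without control 2, 0.0155 without dTAG 1, 0.677 without control 1 and, in the opposite direction, 0.915 without dTAG 2, and the adjusted p was 0.978 with an estimated correlation. Clustered protocadherins, neuronal adhesion genes, had a median of -0.25 (-0.08 and -0.41), with Pcdhb21 at -0.36 and Pcdha2 at 0.14. Their camera adjusted p was 0.319, or 0.0266 with every gene of the list counted and 0.978 with an estimated correlation. Hox genes lie in clusters on chromosomes 2, 6, 11 and 15, and the protocadherins all on chromosome 18. Neighbours share smoothed scores, so counting every gene overstates the evidence. By rotation the adjusted permutation p was 0.631 for the Hox genes, 0.847 for the X-inactivation centre and 0.709 for the protocadherins. Imprinted genes spread from -1.19 at Snrpn to 0.55 at Airn around a median of 0.02. The early housekeeping groups had medians close to 0: -0.04 for ribosomal protein genes (Rps19 -0.55, Rpl39 0.36), -0.06 for oxidative phosphorylation genes (Ndufa5 -1.10, Ndufb4c 0.40), -0.0013 for DNA replication factors (Rpa3 0.53, Pcna -0.32) and 0.03 for architectural and Polycomb factors (Smc3 0.43, Ring1 -0.53). Within replicates 1 and 2 these medians were, in the same order, 0.06 and -0.25, 0.07 and -0.22, -0.0027 and -0.05, and 0.05 and 0.06. The ribosomal and oxidative phosphorylation medians thus had opposite signs in the replicate numbers.

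Lineage markers showed no common direction. The median difference was -0.02 for formative and primed epiblast genes (Wnt8a 0.48, Fgf5 -0.45), -0.03 for neural markers (Dll1 0.36, Neurod1 -0.56), -0.04 for mesoderm markers (Kdr 0.40, Mixl1 -0.26), -0.01 for endoderm markers (Sox17 0.39, Foxa1 -0.37) and 0.07 for trophoblast markers (Krt8 0.42, Tfap2c -0.25). Long neuronal and fragile-site genes, which replicate late with a control mean of -3.07, had a median of -0.09, from -1.01 at Dmd to 0.74 at Macrod2.

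**Figure D3:**
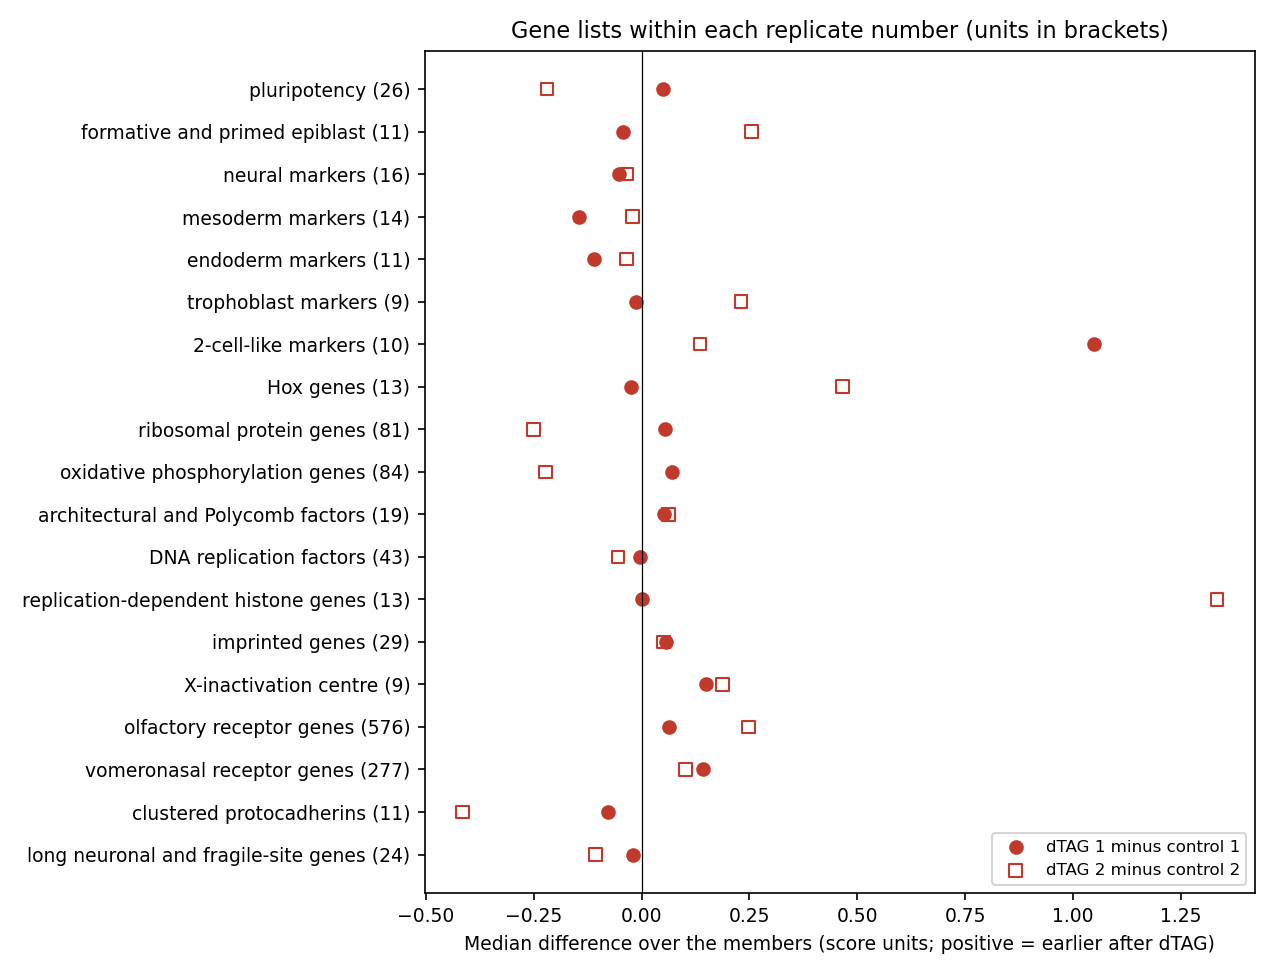
Median difference over the members of each gene list (horizontal axis, score units, positive = earlier after dTAG) for dTAG 1 minus control 1 (filled circles) and dTAG 2 minus control 2 (open squares), with the number of units per list in brackets. The histone genes lie at 0.00 and 1.33 and the 2-cell-like markers at 1.05 and 0.14, the widest gaps between the replicate numbers.

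Timing peaks were counted in each profile as local maxima of the deposited scores, with no minimum prominence. They numbered 6327 and 6541 in controls 1 and 2 and 5957 and 6398 in dTAG 1 and 2, so the dTAG count was lower within each replicate number. The mean difference was -256.5 where the controls differed by 214 peaks, -153 for peaks with a prominence of at least 0.25, where the controls differed by 437, and -183 for windows of 50 kb, where they differed by 227. With a prominence of at least 0.25, 3300 and 3737 peaks remained in controls 1 and 2 and 3084 and 3647 in dTAG 1 and 2. Timing peaks can mark zones where replication begins, but many of those counted were small, so these are not counts of such zones. Minima, again with no minimum prominence, numbered 6333 and 6545 in the controls and 5962 and 6401 after dTAG. The correlation of scores 500 kb apart was 0.690 in control 1, 0.697 in dTAG 1, 0.617 in control 2 and 0.601 in dTAG 2, so it followed the replicate number. The SD of each profile was 3.02, which the shared distributions fix, and it says nothing about the treatment.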

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

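The settings with one distribution for all profiles, the blocked model with a trended robust variance every blocked test of windows over 50 kb, the fits of stretches without 1 profile, camera with the block and an estimated correlation, and r of the pair differences in every setting were chosen after seeing the data. The count of 0 called windows was also 0 under the other window sizes, the scalings, a trended robust variance or a minimum difference, each without the block, and with the replicate block alone; with the block and a trended robust variance together it was 1462, and without 1 profile 0 to 4. The labels do not say what a replicate number marks, and profiles of the same number deviated from their group means together (r = 0.765 over windows). The replicate block took the called stretches of 500 kb from 0 to 330, to 4 on one distribution and to 441 with a trended robust variance, while chromosome centring left 0; without 1 profile the unblocked count was 0 to 1. With 1 residual degree of freedom the blocked calls rest on the pooled variance, whose prior degrees of freedom were 4.87 for 50 kb, 4.89 for 400 kb and 17.9 for 500 kb windows. Switching windows numbered 37 with scores near 0 left out and 846 to 1003 without 1 profile, and shifted windows numbered 2780 at a threshold of 0.25, 109 at 1 and 3651 to 7374 without 1 profile; by construction fewer profiles or a lower threshold let more windows pass. Earlier windows were 273 of 834, 1262 of 2780 at 0.25, 11 of 109 at 1, and 4999 of 6811 without control 1 against 617 of 3720 without control 2, by the offset between replicate numbers. When deciles came from the controls alone, the mean of the latest decile was 0.093, since this selects low control values. That of the earliest decile was -0.085, since high control values are selected there, against 0.013 and -0.049 in the main setting. Without 1 profile the latest decile ran from -0.24 to 0.26 and the earliest from -0.30 to 0.21. Chromosome 13 ran from -0.23 to 0.41 and chromosome X from -0.18 to 0.066. Called gene lists numbered 0 with an estimated correlation, 0 with that and the replicate block, 0 with fry and 1 by rotation. The rotations were not matched on timing, so that 1 call may overstate the evidence. The block itself called 5, adding the Hox genes, and all genes of a list 6. Estimating the correlation from so few residual degrees of freedom could hardly call any list, and with the block every list had an adjusted p of 0.894 by camera. Those counts of 0 therefore do not decide for or against the lists. The adjusted p of the vomeronasal receptors without 1 profile ran from 1.66e-14 to 0.617. The within-group minus between-group r stayed between -0.0127 and -0.00731, the peak difference went from -256.5 to -153 with a minimum prominence, and r of the pair differences stayed between 0.356 and 0.444. GC correction with the block was not run.

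Differences at single genes, none of them called, changed sign mainly when 1 profile was left out, which leaves unequal replicate numbers in the groups. Under chromosome centring Tfcp2l1 was -0.051, Utf1 0.016, Tet1 -0.012 and Jpx 0.026, and on one distribution Tfcp2l1 was -0.011 and Tet1 -0.021; the cause was not tested. Without 1 profile the lowest and highest values were -0.73 to 0.17 for Prdm14, -0.39 to 0.40 for Tfcp2l1, -0.33 to 0.83 for Sall4, -0.067 to 0.26 for Klf4, -0.82 to 0.22 for Lin28a, -0.34 to 0.67 for Tbx3, -0.71 to 0.31 for Dppa3 and -0.65 to 0.54 for Nanog. Those of the next genes were -0.41 to 0.41 for Utf1, -0.57 to 1.14 for Fgf4, -0.14 to 0.20 for Zfp42, -0.85 to 0.43 for Klf2, -0.48 to 0.59 for Dppa5a, -0.43 to 0.77 for Tdgf1, -0.60 to 0.63 for Tet1 and -0.41 to 0.068 for Dnmt3l. Further ranges were -0.20 to 0.018 for Tcl1, -0.16 to 0.34 for Klf5, -0.51 to 0.28 for Pou5f1, -0.0088 to 0.17 for Fbxo15, -1.11 to 0.22 for Fgf5, -0.058 to 0.86 for Kdr, -0.76 to 0.25 for Tfap2c and -1.19 to 0.52 for Usp17la. The last were -0.032 to 0.49 for H2bc1, -0.072 to 0.96 for Zcchc13, -0.35 to 0.29 for Jpx, -0.020 to 0.29 for Pcdha2, -0.24 to 1.72 for Macrod2 and -0.49 to 0.40 for Etv4.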

Other observations

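The correlation of the differences within the replicate numbers and the tests of the mirrored distributions were chosen after the values they use had been seen; the rotation, the removal of timing level and the tests by chromosome were written down first, for patterns found in the data. Genes in this paragraph were chosen after their values were seen. Some genes of the imprinted cluster on chromosome 7 that is lost in Prader-Willi syndrome scored later after dTAG in both replicate numbers. None of them passed the limma test. The fixed list of imprinted genes had a median of 0.02, with 11 of 29 units above 0 in both replicate numbers and 9 below. Snrpn differed by -1.19 (-0.92 and -1.46 within the replicate numbers), Ube3a by -0.72 (-0.89 and -0.56), Ndn by -0.65 (-0.85 and -0.45) and Magel2 by -0.64 (-0.85 and -0.42). Receptor gene clusters lay on both sides. Of the 576 windows with an olfactory receptor gene, 16 were shifted earlier by at least 0.5, such as those of Olfr1234 and Olfr693, and 8 later, such as that of Olfr435. No excess or lack of genes was found in shifted windows against windows of the same timing. The earlier windows held 0.238 protein-coding midpoints each, where windows of the same timing hold 0.25 (permutation p = 0.842 by rotation). The later windows held 0.301 against 0.271 (permutation p = 0.536). Rotated gaps lay mostly between -0.111 and 0.136 for the earlier windows and between -0.088 and 0.107 for the later ones. Gaps within these ranges could not be seen.

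The dTAG minus control differences of the replicate numbers share no library, yet they correlated over the 51425 windows at r = 0.362, and 60.7% of windows had the same sign in both. By decile of timing r ran from 0.622 in decile 6 to -0.077 in decile 9 and -0.176 in the earliest, and by chromosome from 0.079 on chromosome 11 to 0.530 on chromosome 12. Of 1000 rotations of one difference profile along the genome the highest r was 0.0382, which argues against chance between smooth profiles. With all profiles on one distribution r was 0.361. Control and dTAG of a replicate number already hold the same set of scores, so that step changes both nearly alike. It therefore cannot test the mirrored distributions as a cause. After removal of a smooth function of timing level, slope and curvature r was 0.376 ± 0.108 (SD over chromosomes), and the removed part was 2.33% and 3.41% of the variance of the differences, which argues against a bias that is a smooth function of these as the whole cause. The windows in the lowest 1% of the difference in replicate 1 averaged -0.96 in replicate 2, with 88.0% below 0, and those in its highest 1% averaged 0.46, with 70.3% above 0. An effect of YY1 loss, GC content, copy number of subclones, another effect of dTAG, and replicates drawn from shared cultures were not tested against each other and stay open.

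The replicate numbers differed at 15507 windows. Mirrored distributions could explain only part of this, since 7256 windows were still called with all profiles on one distribution. Removal of a smooth function of timing level, slope and curvature from each profile took away 39.2% of the variation between profiles and left 2174 called windows. The bound set beforehand, 5% of windows, was wrong for adjusted calls, of which close to 0 come by chance, so the removed trend could account for part of the difference and the rest stays open. The labels name no biological difference between the replicate numbers, and no biological explanation was tested.

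Chromosomes 12, 14, 16, 17 and 18 were picked because their shifted windows were nearly all later: 212 of 224 windows (94.6%), against 57.2% on the other 15 chromosomes. These windows formed 45 regions, 37 of them later, and a permutation of the directions of all regions over the chromosomes gave a spread as large with p = 0.416, so a small number of independent regions may be enough to give the pattern. With each profile centred on its chromosome means the later share was 79.3% on these chromosomes and 57.6% on the others, a value that lies between what an offset of whole chromosomes and its absence would give, and this stays open.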
